A study of Drosophila melanogaster with 5 samples.

How the data were processed

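Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on Oregon-R Drosophila melanogaster embryos with rabbit antibodies against Pita, ZIPIC and Zw5, 3 zinc-finger DNA-binding proteins described as architectural or insulator proteins. Per the labels' protocols, embryos from a 12 h collection were fixed with 1.8% formaldehyde for 15 min, and 50 µg of chromatin went into each immunoprecipitation. The antigens were residues 550 to 683 of Pita, 84 to 257 of ZIPIC and 98 to 302 of Zw5. Input chromatin and a precipitation with preimmune rabbit serum were the controls. Each of these 5 libraries was sequenced once in 51 cycles of single reads, so there are no replicates. The peak names in the files give chromatin preparation A for Pita and Zw5 and preparation B for ZIPIC, so the preparation differs between ZIPIC and the other 2 proteins and cannot be separated from the antibody. Which preparation the input and preimmune libraries came from is not given in the sources used here, so a fold over a control may compare different preparations.

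The deposited files are 6 MACS2 peak lists, 1 against input and 1 against preimmune serum for each protein. The submitters' processing notes name cutadapt, Bowtie, MACS2 2.1.0.20140616 and the dm3 genome build. Their arguments, the treatment of duplicate reads and the thresholds are not given in the sources used here. The deposited files have the 10 narrowPeak columns and no header line, and per their names peaks were called separately for each library and control. The ratio in the authors' files is the fold enrichment at the summit over the local background of the control. The deposited −log10 p and −log10 q values belong to each peak, and the deposited score was 10 times the −log10 q cut to a whole number in 100% of the peaks. These values are the authors' and were used only to describe, rank or filter peaks within a list. The lowest −log10 q was between 1.85 and 2.31 in the 6 lists. All coordinates are on dm3, counted from 1. In that build, U and Uextra hold unplaced sequence and the Het sequences hold assembled heterochromatin.

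Read counts were not part of the lists, but fold and p together fix the number of fragments stacked at a summit (its pileup) and the background λ, when fold is (pileup + 1)/(λ + 1) and p is the Poisson upper tail. Solving both gave a pileup within 0.05 of a whole read for 100% of the peaks in the 3 input lists and in the ZIPIC preimmune list. In the preimmune lists of Pita and Zw5 only 8.63% and 8.45% came out whole, so no pileups were taken from those. The most common background pileup was 9.18 fragments for Pita, 1.06 for ZIPIC and 10.3 for Zw5. Divided by the shortest interval (218, 152 and 241 bp, which MACS2 sets to the fragment length by default), this is 0.0421, 0.00697 and 0.0427 fragments per bp. The ZIPIC library was thus several times shallower than the others. The median pileup at a summit called against both controls was 224 for Pita (95% exact Poisson interval of a single such count, 196 to 255), 35 for ZIPIC (24.4 to 48.7) and 154.5 for Zw5 (131 to 181). Total reads per library are not known from the lists. These intervals, and all Wilson 95% intervals on shares of peaks, cover counting error only.

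For each protein the main set was the input-list peaks that overlapped a peak of its preimmune list by at least 1 bp ("peaks called against both controls"), with the position and fold of the input list. Overlap between proteins also required 1 bp. It was compared with 1000 circular shifts, each moving all peaks of the second protein on a chromosome arm by 1 random offset, with the highest coordinate in any list as the arm length. The smallest p these shifts can give is 0.001. Regions of all 3 proteins were merged with bedtools 2.31.1. Shares on X were compared by Fisher's exact test, and fold by a permutation test of medians with 100000 resamples, all two-sided, with Benjamini-Hochberg adjustment within each family of 3 or 6 tests. Peaks are the units of all these tests. A p-value therefore describes these lists and not the variation between embryos or precipitations. Spacing was compared with random placement along each arm, and summit distances with summits placed at random inside the second peak. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.

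The overlap test was tested on simulated data built from the ZIPIC and Zw5 input lists. With 0 planted shared peaks, 0 of 20 runs passed p of 0.05, and with 20 planted peaks 20 of 20 did, with a mean of 21.6 found. The unrelated list was made with the same circular shift as the test, and planted peaks were copies. This checks the calculation and not whether such shifts suit real peaks. The pileup solution returned the simulated value for 100% of 2000 peaks simulated with the same formulas. The simulated pileups did not go as low as the lowest ZIPIC ones.

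Main choices and most alternatives were fixed before the data were examined. The alternatives included a −log10 q of at least 5, a fold of at least 5, the same interval counted once, the 300 highest peaks, the input or preimmune lists alone, lists with different controls, summits within 100 bp, 50% reciprocal overlap, and the 5 large arms alone. The split of each overlap by partner and by peak height, with its alternatives, the pileups the correlation of folds over different controls and the shift of single peaks by 5 to 50 kb were added after the data were seen. The regions named were, by the fixed rule, the 10 peaks of highest fold per protein and the 10 best-ranked regions of all 3 proteins, ordered by the worst of the 3 ranks. Because many of the highest ZIPIC peaks lay on Uextra, the 10 highest on the large arms were added. The gene table at hand belongs to another genome release, so gene annotation, gene lists, summit sequence and the placement matched on gene starts were not analysed here, and regions are named by position.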

Results

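Binding of Pita, ZIPIC and Zw5 was mapped in Drosophila embryos from 1 ChIP-seq library per protein, each called against input DNA and against a preimmune serum precipitate. Positions are on dm3. Pita had the most peaks, with 1845 against input and 1402 against preimmune serum. ZIPIC had 575 and 514, and Zw5 had 695 and 355. The median interval against input was 502 bp for Pita, 305 bp for ZIPIC and 387 bp for Zw5. Background read density was 0.0421 fragments per bp in the Pita library, 0.0427 in the Zw5 library and 0.00697 in the ZIPIC library, so peak numbers of ZIPIC and the others come from unequal depth. The chromatin preparation was A for Pita and Zw5 and B for ZIPIC, so for ZIPIC preparation and protein cannot be told apart. With 1 library per protein, no difference in peak number was tested.

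Calling the same precipitate against 2 controls asks which sites are called with either. Pileups came out whole for 8.63% of Pita and 8.45% of Zw5 preimmune-list peaks but 100% of ZIPIC ones. Read scaling may therefore differ between these calls, and the depth of the controls is not known. The shares below may reflect lost depth as well as dependence on the control. Of the Pita input-list peaks, 1381 (74.9%, Wilson 95% interval 72.8 to 76.8) were also called against preimmune serum. The share was 84.9% for ZIPIC (488 peaks, 81.7 to 87.6) and 49.8% for Zw5 (346 peaks, 46.1 to 53.5). Nearly the whole of each preimmune list was found again in the input list, at 99.4% for Pita, 96.3% for ZIPIC and 98.0% for Zw5. Most peaks lost with preimmune serum were low, though the highest reached 26.1-fold over input for Pita, 14.9 for ZIPIC and 19.8 for Zw5. Their median fold over input was 3.34 for Pita, 6.02 for ZIPIC and 3.51 for Zw5, against 18.9, 15.0 and 11.7 for peaks called against both controls. Across those peaks the folds over the 2 controls had a Spearman rho of 0.85 for Pita, 0.78 for ZIPIC and 0.86 for Zw5, where peaks are not independent replicates. Both folds use the same precipitate, so part of this rho is built in. The sites called against both controls are used from here on.

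**Figure D1:**
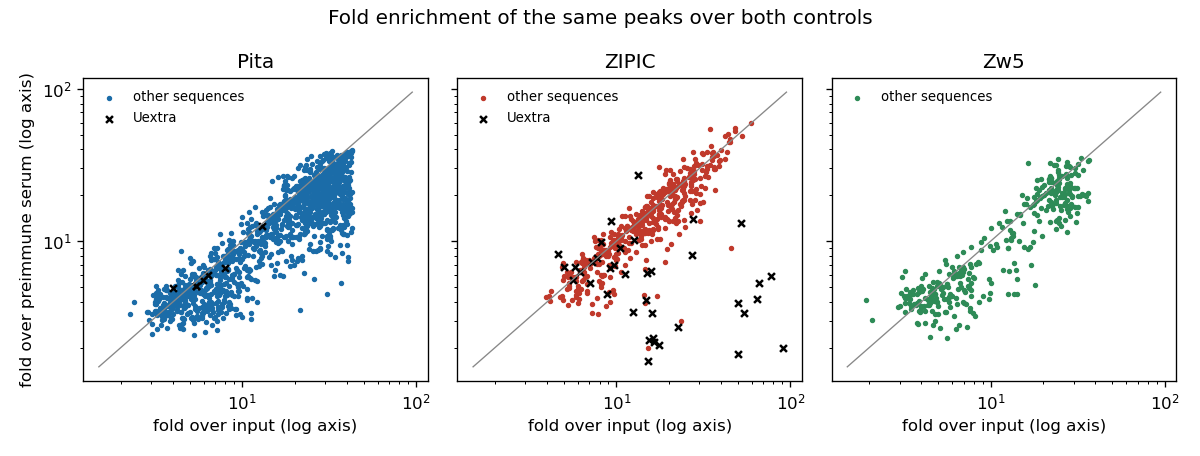
Fold enrichment over input (x axis, log) and over preimmune serum (y axis, log) of each peak called against both controls, 1 panel per protein, with the line of equality and with Uextra peaks as crosses. Most ZIPIC peaks lie near the line, and the Uextra peak of highest fold over input (90.8) has a fold of 1.999 over preimmune serum.

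The 3 proteins were spread over all large chromosome arms, and Pita sites lay on X more often than sites of the other 2. On the 5 large arms, X held 21.3% of Pita peaks (284 of 1332, 19.2 to 23.6), 16.1% of ZIPIC peaks (71 of 442, 12.9 to 19.8) and 12.6% of Zw5 peaks (43 of 342, 9.47 to 16.5). The odds of X for Pita were 1.88 times those for Zw5 (Fisher's exact test, p = 0.000228, adjusted p = 0.000685) and 1.42 times those for ZIPIC (exact p = 0.0164, adjusted p = 0.0246). ZIPIC and Zw5 were not distinguished (odds ratio 1.33, exact p and adjusted p = 0.185). Per Mb up to the highest coordinate, X held 13.1 Pita peaks, against 9.92 to 11.8 on the other large arms. It held 3.27 ZIPIC peaks (3.59 to 4.45 on the others) and 1.98 Zw5 peaks (2.41 to 3.59). The odds for Pita over Zw5 thus join a higher Pita density with a lower Zw5 density on X. No share was tested against arm length. With all input-list peaks the difference between Pita and ZIPIC missed the threshold (odds ratio 1.31, exact p = 0.0497, adjusted p = 0.0745). The small chromosome 4 carried 16 Pita peaks, 1 ZIPIC peak and 0 Zw5 peaks. Among the unplaced sequences, Uextra held 38 ZIPIC peaks, 7 Pita peaks and 0 Zw5 peaks. Over all input-list peaks, chromosome 4 held 26 Pita, 1 ZIPIC and 9 Zw5 peaks and Uextra 41, 63 and 33.

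**Figure D2:**
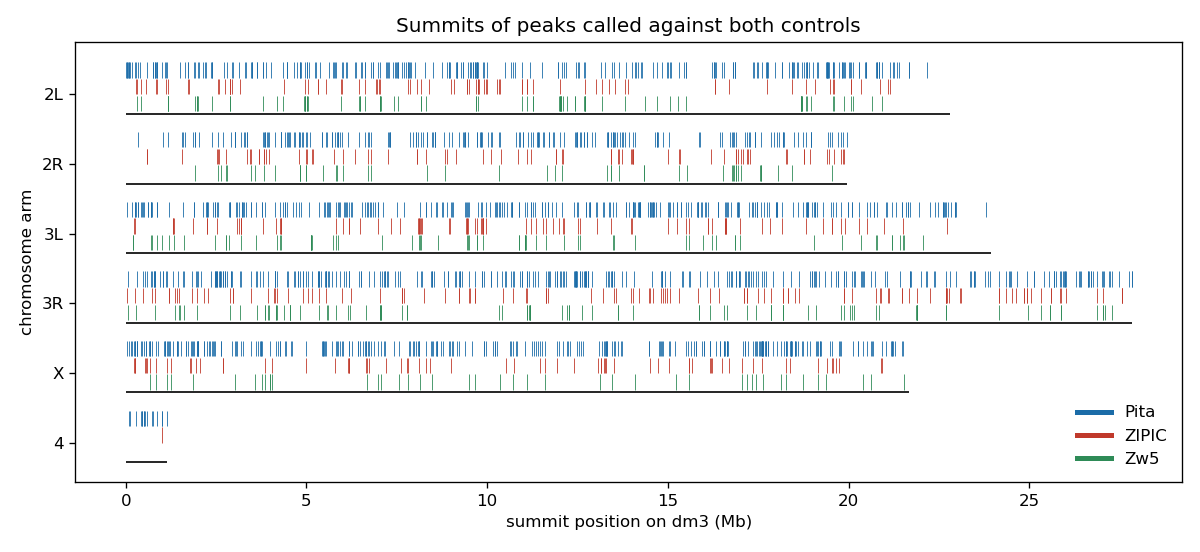
Summit positions on dm3 (x axis, Mb) of peaks called against both controls on arms 2L, 2R, 3L, 3R and X and on chromosome 4, with 1 row of ticks per protein. The black line runs to the highest coordinate in any list. Chromosome 4 shows 16 Pita ticks and 1 ZIPIC tick.

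Zw5, ZIPIC and Pita sites were clustered along the arms, at 9.20, 4.43 and 1.32 times the random share within 5 kb. Another Zw5 summit lay within 5 kb of 27.5% of Zw5 summits (95 of 346, 23.0 to 32.4), against 2.98% in random placements, which never exceeded 7.23%. For ZIPIC the share was 15.6% (12.6 to 19.1) against 3.52% at random. Both exceeded every draw (permutation p = 0.001, the smallest possible). For Pita it was 14.0% (12.3 to 16.0) against 10.7% at random (permutation p = 0.003). Over all input-list peaks the ratio fell to 3.84 for Zw5 and was 4.19 for ZIPIC, and within 20 kb it was 3.55 and 2.32, still above every draw. Within 2 kb the Pita share no longer exceeded random placement (ratio 1.15, permutation p = 0.202).

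The highest Pita peaks reached nearly the same fold. The first 10 had folds over input from 42.0 to 42.8. The highest lay at 2R 8553005 to 8554084 and at 3L 6542862 to 6543917, both 42.8-fold over input, with folds over preimmune serum of 12.2 and 16.6. Next came X 11588518 to 11589365, at 42.7-fold over input and 39.4-fold over preimmune serum, which also carried ZIPIC and Zw5 peaks. The peaks at 2L 18152217 to 18152987, 3R 12795114 to 12796058, X 15990380 to 15991344, 3RHet 2377815 to 2378966 and 3R 21706905 to 21707893 carried neither of the others. Those at X 3999453 to 4000251 and 2L 1909507 to 1910473 also carried Zw5. In all, 218 Pita peaks had a pileup within 10% of the highest value, 436 fragments.

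The highest ZIPIC folds over input lay on unplaced sequence. Of the first 10 ZIPIC peaks, 8 were on Uextra, led by Uextra 5223933 to 5224528 with a fold of 90.8 over input and 1.999 over preimmune serum. The other 2 were 3L 12565332 to 12565908, at 59.8-fold over either control, and 3R 3947820 to 3948456, at 52.6-fold over input and 48.8-fold over preimmune serum. Both carried a Zw5 peak. On the large arms, 9 of the 10 highest ZIPIC peaks carried a Zw5 peak. They included 2L 13176488 to 13177132 (48.1-fold over input), 3L 5806140 to 5806611 (47.8), 3L 8179487 to 8180206 (45.2) and 2L 11268855 to 11269436 (44.8). The exception, 3R 25597721 to 25598122, had a fold of 45.6 over input and 9.03 over preimmune serum.

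The highest Zw5 peaks were held by Zw5 alone. None of the first 10, with folds of 32.7 to 36.8 over input, overlapped a Pita or ZIPIC peak called against both controls. The first was 2L 4187230 to 4188268, at 36.8-fold over input and 34.2-fold over preimmune serum. It was followed by 3R 3951694 to 3952608 (36.5 and 20.6), X 17315805 to 17316529 (36.2 and 33.6), 3R 4557007 to 4558042 (36.2 and 18.4) and 3L 11054052 to 11056153 (35.5 and 19.8).

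Most regions carried 1 of the 3 proteins, and each pair shared far more sites than shifted positions gave. Merging all peaks left 1249 regions with Pita alone, 352 with ZIPIC alone and 196 with Zw5 alone. ZIPIC and Zw5 had the highest ratio of overlap to shifted overlap. A Zw5 peak lay on 87 ZIPIC peaks (17.8%, 14.7 to 21.5), against a mean of 1.33 and a highest value of 7 in 1000 shifts, a ratio of 65.6. Zw5 lay on 83 Pita peaks (6.01%, 4.87 to 7.39) against a mean of 4.95 (ratio 16.8). ZIPIC lay on 70 Pita peaks (5.07%, 4.03 to 6.36) against a mean of 5.12 (ratio 13.7). All 3 pairs exceeded every shift (permutation p = 0.001, the smallest these shifts can give). From the other side, 25.4% of Zw5 peaks (21.1 to 30.3) carried ZIPIC and 24.3% (20.1 to 29.1) carried Pita, and 14.3% of ZIPIC peaks (11.5 to 17.7) carried Pita. Pairs called against the same control share that library. Lists called against different controls overlapped as well, with 89 ZIPIC input-list peaks on the Zw5 preimmune list (ratio 63.4). That count was nearly fixed by the 87 above, because 98.0% of the Zw5 preimmune list was found again in the Zw5 input list. It is therefore no separate test of the shared library. With all input-list peaks the overlaps rose to 201 for ZIPIC and Zw5, 326 for Pita and Zw5 and 132 for Pita and ZIPIC. Over all alternatives the ratio ran from 41.7 to 279 for ZIPIC and Zw5, from 15.7 to 89.6 for Pita and Zw5 and from 12.1 to 53.1 for Pita and ZIPIC, with the highest values for summits within 100 bp.

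All 3 proteins met at 21 merged regions, where independent shifts gave a mean of 0.020 and at most 2 Pita peaks overlapping both others. These shifts also break up the overlap of each pair, so an excess follows from the pairwise sharing. Whether all 3 met more often than the pairwise sharing brings was not tested. In the 21 regions the median fold over input was 27.5 for Pita (range 2.40 to 42.7), 26.8 for ZIPIC (4.85 to 47.8) and 5.55 for Zw5 (3.00 to 12.8). Of the 21 regions, 14 were in the upper part of the Pita ranking, above its median, and 16 in that of ZIPIC, but 1 in that of Zw5. The best-ranked was 3R 794828 to 797208, with folds of 37.8 for Pita, 36.9 for ZIPIC and 12.8 for Zw5. The next, X 11588518 to 11589365, had folds of 42.7, 36.4 and 9.92, and its 3 summits lay within 14 bp. They were followed by 3L 8130406 to 8131173 (37.9, 30.6 and 7.63, summits within 23 bp) and 3R 18181954 to 18182618 (36.6, 26.8 and 7.57, within 55 bp). The remaining 6 of the first 10 were 3R 22706972 to 22707653, X 1130541 to 1131155, 3R 27045096 to 27047175, 3R 5341389 to 5342032, 3L 5805983 to 5806611 and 3R 7047062 to 7047807. Over all 21 regions the summits of the 3 proteins spanned a median of 73 bp.

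Shared sites were high for ZIPIC, low for Zw5 and average for Pita. ZIPIC peaks shared with another protein had a median fold of 21.9 (interquartile range 13.0 to 30.7, 136 peaks) against 13.7 (8.26 to 19.1, 352 peaks) for the rest (permutation test, adjusted p = 1.5e-05). Shared Zw5 peaks had a median of 5.67 (4.43 to 7.54, 150 peaks) against 21.7 (12.4 to 26.6, 196 peaks) for the rest (permutation test, adjusted p = 1.5e-05). Both raw p-values, 1e-05, were the smallest the resamples can give. For Pita the medians were 19.2 (132 peaks) and 18.9 (1249 peaks), which were not distinguished (permutation test, p and adjusted p = 0.906).

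Split by partner and by height, sharing with Zw5 went with high ZIPIC peaks, and sharing with ZIPIC or Pita with low Zw5 peaks. Among the 244 higher ZIPIC peaks, 73 (29.9%, 24.5 to 35.9) carried Zw5, against 14 of the 244 lower (5.74%, 3.45 to 9.40), an odds ratio of 7.01 (Fisher's exact test, p = 1.16e-12, adjusted p = 2.32e-12). Among the 173 higher Zw5 peaks, 10 (5.78%, 3.17 to 10.3) carried ZIPIC, against 78 of the 173 lower (45.1%, 37.9 to 52.5; odds ratio 0.0747, exact p = 4.35e-18, adjusted p = 2.61e-17). Pita lay on 14 of the higher and 70 of the lower Zw5 peaks (odds ratio 0.130, exact p = 1.06e-12, adjusted p = 2.32e-12). With height taken as fold over preimmune serum, the odds ratio was 12.3 for Zw5 on ZIPIC peaks and 0.0821 for Pita on Zw5 peaks. ZIPIC peaks carried Pita about as often in the higher as in the lower set, 37 against 33 (odds ratio 1.14, exact p = 0.699, adjusted p = 0.838). Higher and lower Pita peaks carried ZIPIC 35 times each. They carried Zw5 46 and 37 times (odds ratio 1.26, exact p = 0.365, adjusted p = 0.548), but with the whole Zw5 input list the counts were 192 and 70 (odds ratio 3.41, exact p = 3.35e-17, adjusted p = 6.70e-17).

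**Figure D3:**
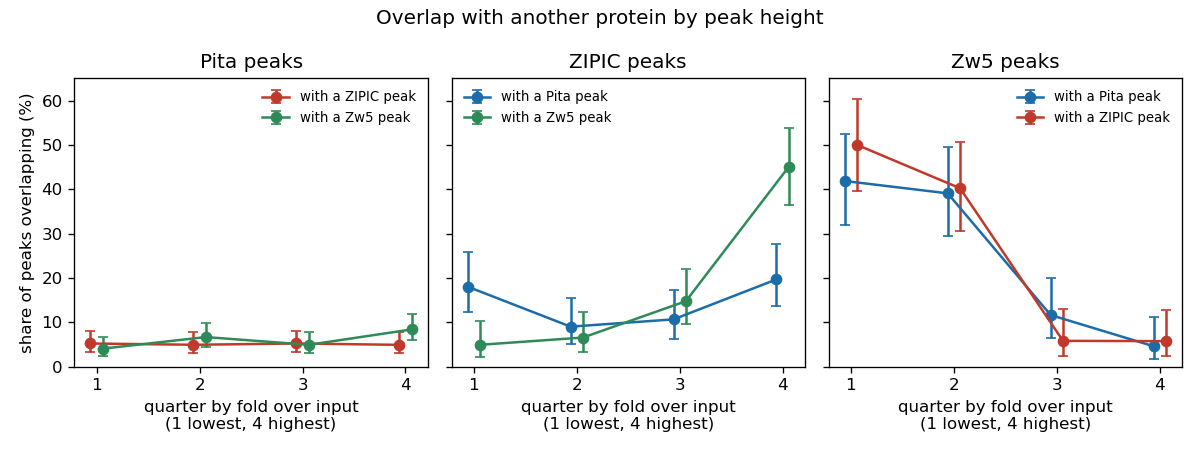
Share of peaks (y axis, percent, with Wilson 95% intervals) that overlap a peak of another protein, by fold over input (x axis, 4 groups of equal size, 1 lowest to 4 highest), 1 panel per protein and 1 colour per partner. Of the 122 ZIPIC peaks in the highest group 45.1% carried Zw5, while 5.75% of the 87 highest Zw5 peaks carried ZIPIC.

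**Figure D4:**
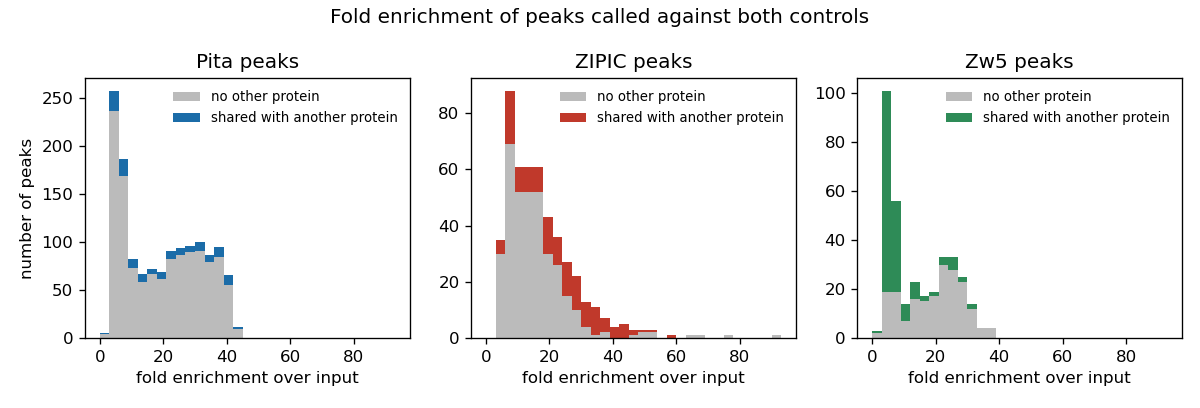
Number of peaks (y axis) by fold enrichment over input (x axis, bins of 3) for each protein, stacked as peaks shared with another protein (colour) and peaks of that protein alone (grey). Shared Zw5 peaks, with a median fold of 5.67, fill the low group, and Zw5 peaks without another protein have a median of 21.7.

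At shared sites the summits lay close together. For ZIPIC and Zw5 the median distance was 22.5 bp over 88 pairs of overlapping peaks, and 78.4% (68.7 to 85.7) lay within 50 bp, against 25.1% for summits placed at random inside the Zw5 peak. Pita and Zw5 summits were 41.5 bp apart in 84 pairs, with 60.7% (50.0 to 70.5) within 50 bp against 22.1% at random. Pita and ZIPIC summits were 50.5 bp apart in 70 pairs, with 50.0% (38.6 to 61.4) within 50 bp against 25.6% at random. Each exceeded every random draw (permutation p = 0.001, the smallest possible). The random draws take no account of where in a peak summits usually lie, so part of this excess may follow from the overlap itself. Across the shared sites, folds over input of Pita and ZIPIC were correlated (Spearman rho 0.48, permutation p = 6e-05, adjusted p = 0.00018, and Pearson r 0.49, permutation p = 2e-05, adjusted p = 6e-05). Those of ZIPIC and Zw5 were correlated by rank (rho 0.37, permutation p = 0.00056, adjusted p = 0.00084) but not by Pearson r (0.015, permutation p and adjusted p = 0.892). Pita and Zw5 folds showed no relation that passed by either measure (rho 0.051, permutation p and adjusted p = 0.644, and r −0.13, permutation p = 0.232, adjusted p = 0.348). Folds over the same control share that library. With Pita over input and ZIPIC over preimmune serum, rho fell to 0.24 (permutation p = 0.0422, adjusted p = 0.0633), and with the controls exchanged it was 0.33 (permutation p = 0.00642, adjusted p = 0.0193). For ZIPIC and Zw5 rho fell to 0.22 and 0.12 in the same order (permutation adjusted p = 0.0633 and 0.277), so neither pair kept its correlation under both exchanges. In the preimmune lists rho was 0.30 for Pita and ZIPIC and 0.29 for ZIPIC and Zw5 (permutation adjusted p = 0.0167 for both). These correlations run across peaks of single libraries, which are not independent replicates.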

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

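The tests in this part were all chosen after the results were seen. Peaks called against input alone, whose overlap with the other proteins was not tested by itself in the planned comparisons, overlapped peaks of the other proteins more often than any of 1000 shifts gave. Of the 349 such Zw5 peaks, 234 (67.0%, Wilson 95% interval 62.0 to 71.8) overlapped a peak of the Pita input list and 114 (32.7%, 28.0 to 37.8) one of the ZIPIC input list, with shifted means of 4.15 and 0.959. Of these, 182 and 87 met a Pita or ZIPIC peak called against both controls. Of the 464 Pita peaks called against input alone, 64 overlapped the Zw5 list and 51 the ZIPIC list. Of the 87 such ZIPIC peaks, 29 overlapped the Pita list and 27 the Zw5 list. These 6 counts share the input library as their control.

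Low Zw5 peaks lay at the high peaks of the other proteins: with the whole Zw5 input list, 82.0% (74.2 to 87.8) of the 122 highest ZIPIC peaks and 42.8% (37.7 to 48.0) of the 346 highest Pita peaks carried Zw5, against 45.1% and 8.38% with the Zw5 peaks called against both controls. Zw5 peaks called against input alone overlapped the Pita and ZIPIC lists called against preimmune serum at least 59.4 times as often as after shifts. Those Pita and ZIPIC peaks were called without input, which argues against the input library alone having made both peaks. The Zw5 peaks rest on input, so input that is low at Pita or ZIPIC sites is not excluded. An equal pull of any antibody on the strongest sites of every protein is argued against. Pita peaks lay on 10.3% (5.54 to 18.5) of the 87 highest Zw5 peaks, below the reverse share. Places that precipitates in general enrich, or that input under-represents, may account for part of the Zw5 peaks at Pita sites, where fold over input divided by fold over preimmune serum had a median of 1.66 at the highest peaks with Zw5 and 1.40 at those without (permutation adjusted p = 0.00518), and stay undecided at ZIPIC sites (1.104 and 1.04, permutation adjusted p = 0.424). Carry-over of ZIPIC reads into the Zw5 library was examined through the ratio of Zw5 to ZIPIC fragments above background. Its median was 0.786 over the 100 of these ZIPIC peaks with Zw5. The upper quartile was 1.69 times the lower, or 1.86 times with the 22 others counted as lowest. The dispersion of 9.49 (3.74 without 4 high ratios) was more than counting gives around a constant share, so carry-over with counting noise alone is argued against. How much noise single libraries add was not measured, so carry-over with such noise, or beside binding, cannot be told apart from binding. Carry-over of Pita reads was not tested. Low occupancy by Zw5 at ZIPIC and Pita sites, contacts between the proteins, or an antibody that also recognises the others stay open and were not tested.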

How the results depend on the processing

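The splits by height with their alternatives, the correlations over different controls, the move of single peaks by 5 to 50 kb and the thinning were chosen after the results were seen. Of 162 values recomputed under an alternative, 137 kept their direction and their side of the threshold, or for counts stayed within 1.5 times. For the control and X shares, staying inside the main Wilson interval was the rule. The tally includes counting the same interval once, which could change nothing because no list held a repeated interval. A −log10 q of at least 5 could change little in the main set. It kept all 1381 Pita peaks, 475 of 488 ZIPIC peaks and 344 of 346 Zw5 peaks. The preimmune lists likewise held mostly sites of the main set. The odds of ZIPIC on higher over lower Pita peaks, just under 1, turned to 1.13 with fold over preimmune serum, 1.33 with the whole ZIPIC input list and 1.08 with summits within 100 bp, never past the threshold; the cause was not tested. Overlap counts followed the list used. With all input-list peaks, 132 Pita peaks overlapped ZIPIC, 326 overlapped Zw5, and 201 ZIPIC peaks overlapped Zw5. With preimmune lists for the first protein and input lists for the second, 264 Pita and 175 ZIPIC peaks overlapped Zw5. Among the 300 highest peaks of each protein the counts were 13, 23 and 56, since fewer peaks entered. With 50% reciprocal overlap, 38 Pita peaks overlapped ZIPIC. The ratio over shifted positions stayed above every shift for all 3 pairs in every alternative run. A fold of at least 5 left 302 Zw5 input-list peaks. The odds of X for Pita over ZIPIC fell to 1.31 with all input-list peaks and no longer passed the threshold, and the clustering of Pita within 2 kb fell to a ratio of 1.15; the cause was not tested. With the first protein over input and the second over preimmune serum, Pita and ZIPIC folds had an r of 0.27 and a rho of 0.24 and ZIPIC and Zw5 folds a rho of 0.22, none past the threshold, and with the controls exchanged the last was 0.12. Correlations that had not passed changed sign without passing, for ZIPIC and Zw5 to an r of −0.011 and −0.089 and for Pita and Zw5 to a rho of −0.15 in either order and −0.051 in the preimmune lists. How much the shared control added to them was not tested. Higher over lower Pita peaks reached odds of 3.41 for carrying Zw5 with the whole Zw5 input list, which adds Zw5 peaks called against input alone. Whether their low height or their dependence on the control raised the odds was not tested. Placement matched on gene starts, gene annotation, gene lists and summit sequence were not run, for want of a dm3 genome and annotation. No paired analysis was possible because each group had 1 library and the labels give no replicate numbers, and for the same reason no library could be left out. By background density the ZIPIC library was the shallowest of the 3 precipitates. Thinned to the ZIPIC background (100 draws), 1094 to 1139 of the 1381 Pita peaks still passed the weakest ZIPIC p against input. The lowest count was 2.24 times the 488 ZIPIC peaks called against both controls, and ZIPIC had 575 peaks against input. Depth alone thus did not account for the difference in calls against input. The call against preimmune serum was not repeated at the lower depth, so for peaks called against both controls this is not settled. For Zw5, 234 to 262 of 346 passed.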

Other observations

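The tests in this part were all chosen after the data were seen. Of the 173 lower Zw5 peaks, 19 had a separate peak of the higher 173 within 5 kb, against a mean of 2.23 and at most 8 in 1000 shifts. That excess is no more than the clustering of Zw5 itself brings. With heights reshuffled among all Zw5 peaks, which keeps the clustering, the mean was 27.5 (95% of reshuffles from 21 to 35), so the tables argue against low peaks flanking high ones as the reason for the clustering.

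Sharing between proteins exceeded what neighbourhoods of 5 to 50 kb gave. If shared neighbourhoods of 5 to 50 kb were the cause, peaks moved by that much would overlap as often as in place, but the observed overlap was at least 12.1 times higher in all 3 pairs. Placement matched on gene starts was not run. Sharing particular to these proteins is thus not told apart from common use of gene starts or similar sites. Beyond the shared sites, ZIPIC peaks without Zw5 had a Zw5 peak within 5 kb in 22 cases against a mean of 9.66 (permutation adjusted p = 0.006). Pita peaks without ZIPIC had ZIPIC within 5 kb in 62 cases against 45.9 (permutation adjusted p = 0.018), and Pita peaks without Zw5 had Zw5 within 5 kb in 21 cases against 33.7 (permutation adjusted p = 0.99 for an excess). The shifted counts keep direct overlaps, which the observed counts leave out. The shifted means are therefore somewhat too high, and no shortfall can be read from them.

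The ZIPIC folds on Uextra may reflect DNA that control precipitates also enrich or that input under-represents. Over the 38 Uextra peaks the median of the fold over input divided by the fold over preimmune serum was 2.45 (interquartile range 1.048 to 8.09), against 1.022 (0.936 to 1.24) on the 5 large arms, which is what this explanation needs. Binding of ZIPIC to repeats held in unplaced sequence was not tested and stays open for the peaks with like folds over both controls.

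The ceiling of the Pita folds is consistent with 1 read kept per position and strand. Such a filter limits the pileup to the number of start positions in reach, 436 for fragments of 218 bp on 2 strands. The highest Pita pileup over that limit was 1.00, and 218 peaks lay within 10% of it. For Zw5 the highest was 470 of a possible 482, with 15 peaks within 10%, and for ZIPIC 186 of 304. No biological explanation was tested. Order among the strongest Pita sites may therefore be lost, while ZIPIC, with the shallowest library, stayed below its limit.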
